A study of Mus musculus with 27 samples.

How the data were processed

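RNA of mouse intestinal epithelium and intestinal tumours was sequenced on a NovaSeq sequencer, per the labels' protocols. The same protocols name TruSeq RNA Sample Prep v2 or a stranded kit with ribosomal RNA depletion, without saying which library had which kit, and the series description speaks of polyA transcriptomes. Reads were trimmed with fastp, aligned with STAR to GRCm38 and analysed with limma, per the submitters' processing notes. Versions of these tools, the counting step and its use of strand are not stated there.

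In the table with the transgene, the deposited values of 17440 genes are CPM, per the file headers. Every nonzero value of these 9 libraries was, within 0.02, a whole number of reads times what 1 read is worth in that library, so library totals and reads per gene were recovered from the deposited CPM. The values stayed CPM for the main tests. Another 12 columns of per-sample values in that table carry no sample of this series and were not used here. In the table with the knockout, the deposited values of 15176 genes are a normalised count signal on a common library size, per the file headers, with column totals of 6307850 on average. What 1 read is worth varied there between genes and libraries, so reads were not recovered, and depth is an estimate. In 8 of its 18 libraries fractions of up to 0.497 normalised counts, or 0.0788 nCPM as defined below, stood in place of zeros. The other 10 held exact zeros. Of these, the library whose labels disagreed on its group also held 62 fractions, of up to 0.500 normalised counts (0.0793 nCPM). A value below 0.5 normalised counts was read as no count. For 1 gene that occurred in duplicate, 1 of the 2 copies was dropped. A list of gene names and a copy of the transgene table were not used here. The highest share of identical values between 2 libraries was 0%.

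Values of the knockout table were multiplied by 0.159, which brings the mean column total to the scale of CPM, and are given as nCPM. They are not CPM of each library, and the 2 tables were fitted apart. Samples were grouped by genotype and treatment. Of 27 samples, 26 entered the tests, and the library with disagreeing labels was left out. In each table a gene was tested where at least 3 (transgene table) or 5 libraries (knockout table), the size of the smallest group, had a value of at least 1 CPM or nCPM. That left 15173 and 14806 genes. On log2(value + 1), limma 3.58.1 in R 4.3.3 fitted 1 mean for each of the 3 groups of a table, with moderated variances (trend and robust set to true). The 3 pairwise differences of each table were tested on both sides, with Benjamini-Hochberg adjustment over the genes of the table and a threshold of 0.05. All adjusted p-values for genes are from this fit. For Fosl1 an exact permutation test was added. Errors beside means are SD between mice, and intervals are 95%.

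Of 48 gene lists written before the data were examined, 45 had at least 4 tested genes. They were tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Beside it stand camera with an estimated correlation and fry, a test of the list alone. Counts of list members that passed are over all genes of the table unless said to be adjusted over the list alone. Sets of genes at least 2-fold higher in the transgene table were followed in the knockout table with camera. A fold against a group without a read used a floor of 3 reads per library. Chromosome positions are those of GENCODE M21 on GRCm38, matched by gene ID.

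The genes named were chosen by a rule that was also written before the data were examined, as were the tests and most alternatives. It takes up to 10 genes with the largest positive and 10 with the largest negative change among those past the threshold. They need a mean of at least 5 CPM or nCPM in the higher group and no overlap between the libraries of the 2 groups. Predicted gene models and receptor segments of lymphocytes are left out. To these it adds Fosl1, Braf, up to 4 members of a described list with the smallest adjusted p, and members that go against their list. Olfm4 in the first comparison, Ccdc85b and Gstp1 near Fosl1, the genes compared across tables and those of the closing part were named after their values were seen. Results of 2 genes that the rule or the text would name are not reported here.

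Alternatives planned were pseudocounts of 0.25 and 5, no filter, a filter at 5 CPM or nCPM, TMM and median-ratio rescaling of the deposited values, a fit of the 2 compared groups alone, array weights, the number in the titles as a replicate block, and leaving out each library in turn. Added after the data were seen were edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads of the transgene table, fits without knockout libraries 1 and 2, fits without the 3 libraries of highest mitochondrial share, and rescaling without mitochondrially encoded genes.

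The gene fit, its comparisons and camera were tested on simulated data, with 200 genes changed by 1.5-fold, 2-fold or 4-fold. A separate list of genes was raised 2-fold for camera. Every library took the real mean of the reference group and 1 spread per gene, averaged over the 3 groups of the table. For knockout against Braf (14806 genes), 10.4%, 47.8% and 80.3% of those were called, with 5 unchanged genes called. For Braf against control the shares were 8.96%, 22.4% and 74.2% in the transgene table (15173 genes) and 11.9%, 38.8% and 74.2% in the knockout table. For transgene against control they were 1.49%, 17.9% and 57.6%, for transgene against Braf 1.49%, 47.8% and 78.8%, and for knockout against control 10.4%, 47.8% and 77.3%. None was called in the wrong direction. Fry and the gene sets followed between tables were not simulated. Genes were drawn independently and few were changed. These rates thus need not hold where genes move together, most of them change or groups differ in spread.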

Results

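RNA was sequenced from intestinal epithelium and intestinal tumours of mice, and 27 libraries were described in 2 deposited tables of expression per gene. In these mice a tamoxifen-inducible Cre recombinase under the villin promoter acts in the intestinal epithelium. A protocol given for all samples has mice of 6 weeks receive 5 mg of tamoxifen by gavage for 2 days. The labels of single samples repeat that dose only for the knockout libraries and the library without a group. The Braf group then expressed the activated allele of the kinase gene Braf, V637E, the mouse counterpart of human V600E. In the knockout group, floxed alleles of Fosl1, the gene of the AP-1 transcription factor also called Fra-1, were deleted together with activation of Braf. The Fosl1 transgene group carried a tetracycline-switchable Fosl1 gene and was fed doxycycline at 2000 mg/kg of chow. The labels give doxycycline to no other group, so an effect of the drug cannot be told apart in any comparison of this group. Titles of these libraries read FTg-ON, which names the transgene as on. The labels name no transactivator for the switchable gene, however, so whether doxycycline switched it on was not checked. The group is called transgene here by its label only. Controls received oil in place of tamoxifen. Titles named adenoma as the source of the Braf, transgene and knockout libraries and normal tissue as that of the controls, so each comparison with control also compared tumour with normal tissue. No batch or sequencing run was given in the labels, so no batch could be checked. Library names hold numbers whose meaning is not given. They were lower in the knockout than in the controls deposited beside it and in most of its Braf libraries. In the transgene libraries they were higher than in the Braf and control libraries deposited beside them. A batch that followed these numbers could not be told apart from the groups.

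The table with the transgene held 3 control, 3 Braf and 3 Fosl1 transgene libraries. Library totals were 14.0, 12.8 and 13.2 M reads in control 1 to 3. Braf libraries 1 to 3 held 14.2, 12.4 and 13.6 M reads. In transgene libraries 1 to 3 the totals were 15.5, 13.5 and 14.9 M reads. A count of 3 reads, used as a floor where a gene had no read in a group, stood for 0.225 CPM in controls, 0.224 in Braf and 0.206 in transgene libraries, and covered counting error only. Replicates correlated across genes at 0.972 to 0.984 in controls, 0.958 to 0.964 in Braf and 0.963 to 0.971 in transgene libraries.

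The table with the knockout held 6 control libraries (4 to 9), 5 Braf libraries (4 to 8), 6 libraries of Braf with Fosl1 knockout (1, 2, 3, 5, 6 and 7) and 1 library whose labels disagreed on its group. Its values had been brought to a common library size, so depth was estimated from the steps between low values. Values of this table are given as normalised counts brought to the scale of CPM by 1 factor for the whole table (nCPM). Estimates were 5.38, 5.48, 6.76, 6.80, 6.57 and 6.64 M reads in control 4 to 9, and 6.14, 5.56, 6.97, 6.29 and 6.78 M in Braf 4 to 8. Knockout libraries 1, 2, 3, 5, 6 and 7 stood at 6.26, 4.12, 6.05, 6.36, 5.72 and 6.49 M reads, and the library without a group at 7.80 M. Replicates correlated at 0.973 to 0.986 in controls, 0.908 to 0.962 in Braf and 0.904 to 0.972 in the knockout. The 2 tables had been normalised separately, so values were tested only within a table and levels are not compared between them.

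Fosl1 itself (ENSMUSG00000024912, chromosome 19, 5447547 to 5455946 on the plus strand, GRCm38) was the first gene examined. It had 0 reads in each of the 3 control libraries of the transgene table. Braf libraries 1 to 3 had 59, 53 and 72 reads, or 4.15, 4.27 and 5.31 CPM, a mean of 4.57 ± 0.637 CPM (SD, n = 3) and at least 20.3-fold over the control floor (log2 change 2.47, adjusted p = 5.1e-06). Transgene libraries had 56, 50 and 49 reads, or 3.62, 3.70 and 3.30 CPM, a mean of 3.54 ± 0.211 CPM and at least 15.7-fold over the same floor (log2 change 2.18, adjusted p = 1.2e-05). Between transgene and Braf the log2 difference was −0.29 (95% interval −0.74 to 0.16, adjusted p = 0.342), so Fosl1 RNA was not higher with the transgene than with Braf. The exact permutation p was 0.1 in each of these 3 comparisons, the lowest that 20 assignments of 3 against 3 libraries allow. Reads from the transgene and from the endogenous gene were counted together, so this level does not show that the transgene was switched on. Fosl1 was not analysed in the knockout table, so the deletion could not be read from the values.

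**Figure D1:**
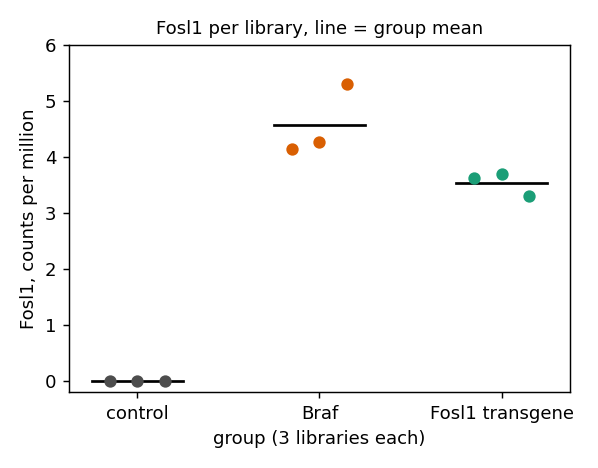
Fosl1 in CPM in each library of the transgene table. Means were 0 in control, 4.57 in Braf and 3.54 with the transgene (n = 3 each).

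The first comparison asked which genes differed between Braf adenomas and control epithelium, in the 3 Braf and 3 control libraries of the transgene table. Among the genes that met the naming rule, Clu rose most (ENSMUSG00000022037, chromosome 14, 65968483 to 65981547), a marker of revival stem cells in regenerating intestine, at 10319 ± 1137 against 7.15 ± 3.85 CPM (SD, n = 3 in each group, log2 change 10.40, adjusted p = 2.9e-08). Fetal and regenerative markers rose in 14 of 16 members (list adjusted p = 3.8e-08; adjusted p = 0.159 with an estimated correlation). Anxa1 was at 467 ± 137 against 1.05 ± 0.321 and Il1rn at 471 ± 74.8 against 1.04 ± 0.570 CPM. Atg9b reached 1481 ± 235 against 0.301 ± 0.133 and Tnfrsf11b, the gene of osteoprotegerin, 274 ± 40.6 against 0.272 ± 0.104 CPM. Enterocyte markers fell in 19 of 20 members: lactase (Lct, ENSMUSG00000026354, chromosome 1, 128284756 to 128328318) was at 0.314 ± 0.276 against 1658 ± 400.5, aminopeptidase N (Anpep) at 10.3 ± 7.95 against 6175 ± 751 and sucrase-isomaltase (Sis) at 4.20 ± 3.55 against 1914 ± 477 CPM (list adjusted p = 6.4e-13; adjusted p = 0.317 with an estimated correlation). Enpp7 had no read in any Braf library, at least 3019-fold below its control mean of 678 ± 327 CPM.

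Targets and feedback regulators of ERK signalling rose in 15 of 18 members (list adjusted p = 7.5e-06; adjusted p = 0.159 with an estimated correlation). Ier3 was at 82.3 ± 22.2 against 5.29 ± 0.255, Dusp4 at 73.1 ± 25.7 against 5.09 ± 0.846 and Etv4 at 126 ± 29.4 against 5.05 ± 2.65 CPM. Of 12 AP-1 genes, 5 rose and 1 fell, and next to Fosl1 the rises included Junb at 387 ± 35.1 against 140.2 ± 30.4, Jund at 58.6 ± 12.8 against 25.4 ± 4.82 and Atf3 at 24.3 ± 6.51 against 7.93 ± 4.39 CPM, with no call for the list (adjusted p = 0.25). Wnt targets rose in 14 of 16 members (list adjusted p = 1.1e-05; adjusted p = 0.317 with an estimated correlation). Notum was at 196 ± 65.5 against 0.820 ± 0.273 and Nkd1 at 328 ± 138 against 1.26 ± 0.901 CPM. Stem cell markers parted, 9 higher and 2 lower of 14: Tnfrsf19 rose to 70.5 ± 13.3 against 1.88 ± 0.312 and Sox9 to 167 ± 10.4 against 20.4 ± 2.12 CPM, whereas Olfm4 fell to 17.9 ± 12.1 against 386 ± 111 CPM. Gastric markers, typical of serrated lesions, rose in 10 of 15 members (list adjusted p = 9.7e-04; adjusted p = 0.481 with an estimated correlation). Cathepsin E (Ctse) was at 1255 ± 34.2 against 25.1 ± 12.2 and Vsig1 at 57.2 ± 7.06 against 0.860 ± 0.692 CPM. Cell-cycle inhibitors and p53 targets rose in 12 of 15 members (list adjusted p = 9.7e-04; adjusted p = 0.332 with an estimated correlation). Phlda3 was at 205 ± 22.5 against 1.83 ± 0.458 and Cdkn2a, the gene of p16 and p19Arf, at 70.2 ± 26.1 against 0.172 ± 0.106 CPM.

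Genes of matrix breakdown and plasminogen activation rose in 12 of 14 members (list adjusted p = 3.1e-04; adjusted p = 0.317 with an estimated correlation). Plat was at 307 ± 113 against 0.422 ± 0.177 and Plaur at 194 ± 76.4 against 2.49 ± 0.677 CPM. Inflammatory mediators rose in 13 of 17 members (list adjusted p = 0.00582; adjusted p = 0.436 with an estimated correlation). Tnf was at 16.7 ± 2.29 against 0.983 ± 0.610 and Duoxa2 at 136 ± 64.1 against 3.64 ± 1.41 CPM. Enteroendocrine markers were lower in 13 of 14 members (Chga 2.88 ± 1.69 against 76.1 ± 17.3 CPM; list adjusted p = 2.1e-08, and adjusted p = 0.228 with an estimated correlation). Xenobiotic and retinol metabolism was lower in 14 of 15 (Cyp2b10 0.793 ± 0.398 against 264 ± 132 CPM; list adjusted p = 5.5e-09, and adjusted p = 0.317 with an estimated correlation). Cholesterol synthesis rose in 9 of 14 (6 after TMM scaling; list adjusted p = 0.0326, and adjusted p = 0.629 with an estimated correlation), a call that ended without control 3 (0.0529) or Braf 2 (0.14). T cell genes fell in 7 of 11 members (list adjusted p = 0.00408; adjusted p = 0.553 with an estimated correlation). Cd8a was at 0.504 ± 0.539 against 21.4 ± 9.20 and Gzmb at 0.739 ± 0.562 against 26.0 ± 10.8 CPM. Other lists of cell types and RNA quality moved too. Endothelial markers rose in 8 of 12 (list adjusted p = 0.0415; adjusted p = 0.639 with an estimated correlation), a call that ended without control 1 (0.0538), control 3 (0.0979), Braf 1 (0.0735) or Braf 3 (0.0521). Neutrophil markers rose in 5 of 5 and smooth muscle markers in 8 of 9 without a call for the list (adjusted p = 0.0661 and 0.0583). Of the smooth muscle markers 1 fell, and the sum over that list was 218 ± 78.4 CPM in Braf against 201 ± 7.01 in control. Mitochondrially encoded genes fell in 8 of 11 (list adjusted p = 0.00571; adjusted p = 0.518 with an estimated correlation). Bulk tissue does not separate a change in the mix of cells from a change within cells.

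In all, 7751 of 15173 tested genes changed at an adjusted p below 0.05, 5020 higher and 2731 lower, and 2758 and 1705 of them by at least 2-fold. The split depended on scaling, because the median gene was 0.27 log2 higher in Braf, and after TMM scaling 3791 genes were higher and 3785 lower of 7576. Fosl1 and the other genes named above for this comparison were far beyond that shift. P-values of limma for single genes rest on the spread between the mice sampled here. Camera at the preset correlation sets a list against the other genes, and Fisher's test counts genes. Their p-values do not measure that spread.

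The Braf comparison was repeated in other mice, the 5 Braf and 6 control libraries of the knockout table. Clu again rose most of the genes that met the rule, to 4947 ± 2789 against 6.28 ± 1.35 nCPM (SD, n = 5 and 6, log2 change 9.23, adjusted p = 1.2e-12), followed by Atg9b at 823 ± 272 against 0.941 ± 0.519 and, among fetal and regenerative markers, Anxa1 at 326 ± 120.5 against 1.08 ± 0.415 and Il1rn at 399.9 ± 95.8 against 1.66 ± 1.07 nCPM. All 16 members of that list rose (list adjusted p = 2.0e-08; adjusted p = 0.238 with an estimated correlation). MAPK output rose in 17 of 18 members (Ier3 83.2 ± 21.4 against 5.61 ± 0.462 nCPM; list adjusted p = 1.0e-05, and adjusted p = 0.0902 with an estimated correlation). Gastric markers rose in 15 of 16 (list adjusted p = 2.7e-05; adjusted p = 0.279 with an estimated correlation). Tff2 was at 2677 ± 2748 against 12.3 ± 4.39 and Anxa10 at 677 ± 258 against 9.59 ± 5.21 nCPM. Enterocyte markers fell in 19 of 20 (list adjusted p = 7.4e-11; adjusted p = 0.279 with an estimated correlation). Lct was at 1.20 ± 0.690 against 2064 ± 236 nCPM. Distal genes fell in 7 of 8 members (list adjusted p = 1.2e-08; adjusted p = 0.0672 with an estimated correlation). The ileal bile acid binding protein gene Fabp6 was at 0.595 ± 0.402 against 605 ± 219 and Cubn at 1.95 ± 1.07 against 747 ± 210.1 nCPM. Colon and caecum genes fell in 5 of 9 and rose in 2 (list adjusted p = 0.0133, and adjusted p = 0.238 with an estimated correlation). Proximal genes fell in 5 of 8 and rose in 3 without a call for the list (adjusted p = 0.0738). Falls were thus not particular to the distal list. Proliferation genes rose in 15 of 18 members here, or 10 after TMM scaling, with Rrm2 at 85.6 ± 19.1 against 18.4 ± 8.31 nCPM (list adjusted p = 0.0228; adjusted p = 0.605 with an estimated correlation), against 8 of 18, or 2 after TMM scaling, in the transgene table (adjusted p = 0.158). Markers of other cells rose as well: macrophages in 10 of 11 with 0 lower, or 9 and 1 after TMM scaling (list adjusted p = 0.00496; adjusted p = 0.279 with an estimated correlation), neutrophils in 4 of 4 (list adjusted p = 0.0323; adjusted p = 0.279 with an estimated correlation) and fibroblasts in 11 of 12 (list adjusted p = 0.00656; adjusted p = 0.414 with an estimated correlation). Endothelial markers rose in 9 of 11 (list adjusted p = 0.0133; adjusted p = 0.422 with an estimated correlation) and smooth muscle markers in 8 of 10 (list adjusted p = 0.0122; adjusted p = 0.434 with an estimated correlation). T cell markers went the other way, 7 of 8 lower (list adjusted p = 0.00291, and adjusted p = 0.328 with an estimated correlation). Of the fibroblast markers 1 fell, and the sum over that list was 351 ± 238 nCPM in Braf against 313 ± 52.3 in control, a difference within the spread. Mitochondrially encoded genes fell in 10 of 13 (list adjusted p = 6.3e-04; adjusted p = 0.409 with an estimated correlation).

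Of 14806 genes tested in the knockout table, 9117 changed between Braf and control, 6712 higher and 2405 lower (median shift 0.42 log2, and 4286 higher and 4370 lower of 8656 after TMM scaling). Among the 14185 genes tested in both tables, 4520 rose in both where 2272 were expected from the 2 counts, n1 × n2 / N, and 2004 fell in both where 428 were expected. Clu, Atg9b, Anxa1 and Il1rn were among the 10 largest rises of each table, and Lct, Enpep, Anpep and Enpp7 among the 10 largest falls. Only 5 genes changed in opposite directions, and 98.7% of the genes called in the transgene table had the same sign in the knockout table (correlation of log2 changes 0.940).

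The third question was how adenomas with the Fosl1 transgene and no Braf mutation differed from control, in the 3 transgene libraries against the same 3 controls. Wfdc18, a gene for a secreted protease inhibitor, rose most of the genes that met the rule, to 1431 ± 469.8 against 0.152 ± 0.262 CPM (SD, n = 3 in each group, log2 change 10.25, adjusted p = 1.6e-06), and Clu reached 4131 ± 1309 against 7.15 ± 3.85 CPM (log2 change 9.04, adjusted p = 5.8e-08). Other rises named by the rule were Lcn2, the gene of lipocalin 2, at 574 ± 274 against 0.280 ± 0.180, Lrg1 at 458 ± 214 against 0.278 ± 0.167 and Serpina3n at 337 ± 89.8 CPM, the last at least 1496-fold over controls without a read. All 16 Wnt targets rose (list adjusted p = 2.4e-05; adjusted p = 0.243 with an estimated correlation). Nkd1 was at 785 ± 209 against 1.26 ± 0.901, Notum at 348 ± 96.1 against 0.820 ± 0.273 and Lef1 at 24.8 ± 4.98 against 0.126 ± 0.0882 CPM. Each of the 14 matrix protease and plasminogen genes rose as well (list adjusted p = 2.4e-05; adjusted p = 0.243 with an estimated correlation). Plat was at 458 ± 6.93 against 0.422 ± 0.177, Mmp14 at 341 ± 31.2 against 25.4 ± 3.98 and Adam8 at 91.3 ± 31.1 against 2.23 ± 0.559 CPM. Fetal and regenerative markers rose in 15 of 16 (Anxa1 279 ± 44.2 against 1.05 ± 0.321 CPM; list adjusted p = 3.3e-06, and adjusted p = 0.243 with an estimated correlation), and MAPK output in 13 of 18 (Phlda1 124 ± 32.0 against 2.50 ± 0.143 CPM; list adjusted p = 0.00612, and adjusted p = 0.243 with an estimated correlation).

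Markers of epithelial-to-mesenchymal transition rose in 11 of 12 members and fell in 1 (list adjusted p = 0.0136; adjusted p = 0.538 with an estimated correlation). Sparc was at 283 ± 78.9 against 1.79 ± 1.01 and Cdh2 at 8.19 ± 3.59 against 0.0253 ± 0.0437 CPM. Tgfbi was the 1 gene that fell, 118 ± 24.2 against 232 ± 45.1 CPM. Inflammatory mediators rose in 15 of 17 (list adjusted p = 0.00244; adjusted p = 0.458 with an estimated correlation). Ccl2 was at 16.8 ± 8.75 against 0.0519 ± 0.0899 and S100a9 at 13.3 ± 0.414 against 0.0259 ± 0.0449 CPM. Macrophage markers rose in 11 of 12 (list adjusted p = 0.019; adjusted p = 0.527 with an estimated correlation), and neutrophil markers in 4 of 5 without a call for the list (adjusted p = 0.0693). T cell markers were lower in 5 of 11 and higher in 1 (list adjusted p = 0.0112; adjusted p = 0.538 with an estimated correlation). Genes of stromal cells rose too: fibroblast markers in 11 of 12 (Col1a1 335 ± 145 against 1.36 ± 1.79 CPM; list adjusted p = 0.00625, and adjusted p = 0.527 with an estimated correlation) and endothelial markers in 11 of 12 (Cdh5 44.7 ± 9.83 against 0.207 ± 0.295 CPM; list adjusted p = 0.00161, and adjusted p = 0.526 with an estimated correlation). Of the fibroblast markers 1 fell. Enterocyte markers fell in 19 of 20 (list adjusted p = 2.7e-11, and adjusted p = 0.338 with an estimated correlation). Lct was at 24.5 ± 26.2 against 1658 ± 400.5 and Vil1 at 508 ± 86.4 against 2791 ± 435 CPM. Xenobiotic and retinol metabolism fell in all 15 (Cyp2b10 1.49 ± 0.729 against 264 ± 132 CPM; list adjusted p = 1.0e-09, and adjusted p = 0.243 with an estimated correlation).

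With the transgene, 9743 genes changed from control, 7085 higher and 2658 lower, of which 4410 and 1598 by at least 2-fold. The median gene was 0.47 log2 higher, and TMM scaling gave 4785 higher and 4333 lower of 9118. Against control, 4466 genes rose both with Braf and with the transgene where 2344 were expected, and 2112 fell in both where 478 were expected. Clu, Plat, Atg9b and Nkd1 rose in both, and 52 genes went in opposite directions. The log2 changes of the 2 comparisons correlated at 0.841 with a covariance of 1.78. Because both used the same 3 controls, unchanged groups simulated against those controls already correlated at 0.501, with a covariance of only 0.0496, a difference of 1.73. Part of the excess may still come from the shared controls, and 3 controls are too few to divide into parts of at least 2.

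**Figure D2:**
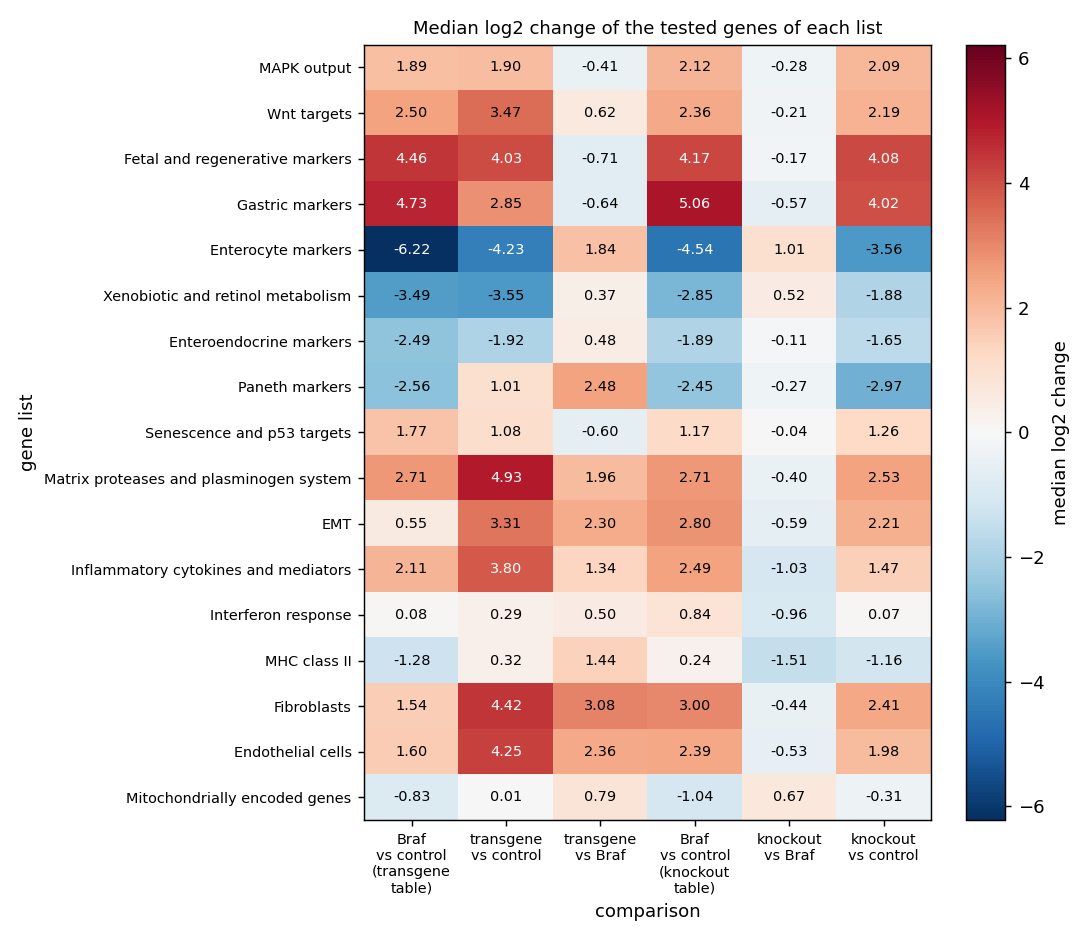
Median log2 change of the tested genes of 17 lists in the 6 comparisons. Enterocyte markers had a median of −6.22 in Braf against control and 1.01 in knockout against Braf. After TMM scaling, medians changed sign for interferon response genes against control (0.08 to −0.17 in Braf of the transgene table, 0.29 to −0.12 with the transgene and 0.07 to −0.22 in the knockout). MHC class II genes did so against control (0.32 to −0.13 with the transgene and 0.24 to −0.17 in Braf of the knockout table). Mitochondrial genes with the transgene against control (0.01 to −0.39) and p53 targets in knockout against Braf (−0.04 to 0.13) did as well.

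The transgene and Braf libraries were then compared directly, to find what set the 2 kinds of adenoma apart. By the labels only the transgene mice were fed doxycycline, so its effect cannot be told apart from that of tumour origin. Of the genes that met the rule, Serpina3n rose most, to 337 ± 89.8 against 3.41 ± 4.65 CPM (SD, n = 3 in each group, log2 change 6.74, adjusted p = 4.1e-04), and Lcn2 was at 574 ± 274 against 24.3 ± 34.4 CPM (log2 change 5.48, adjusted p = 0.00714). The Wnt inhibitor gene Wif1 was at 338 ± 88.5 against 15.0 ± 18.6 and the stem cell receptor gene Lgr5 at 85.4 ± 10.5 against 4.89 ± 6.35 CPM (log2 change 4.41, adjusted p = 0.00249), although the stem cell list as a whole, 3 higher and 2 lower of 14, had an adjusted p of 0.869. Fibroblast markers rose in all 12 members (list adjusted p = 2.5e-06; adjusted p = 0.659 with an estimated correlation). Fbln1 was at 119.8 ± 4.35 against 12.4 ± 4.85 and Postn at 44.6 ± 25.1 against 2.34 ± 1.40 CPM. Markers of epithelial-to-mesenchymal transition rose in 10 of 12 (list adjusted p = 2.2e-05; adjusted p = 0.659 with an estimated correlation). Vim was at 227 ± 169 against 14.6 ± 9.55 and Tgfbi at 118 ± 24.2 against 21.3 ± 12.7 CPM. Endothelial markers rose in 10 of 12 (list adjusted p = 2.2e-05; adjusted p = 0.659 with an estimated correlation). Cdh5 was at 44.7 ± 9.83 against 5.00 ± 3.35 CPM. Prox1, which also marks enteroendocrine and lymphatic cells, was at 214 ± 68.3 against 3.72 ± 4.70 CPM. Its level, well above that of Cdh5, need not come from endothelial cells. Smooth muscle markers rose in 7 of 9, or 6 after TMM scaling (list adjusted p = 0.00238; adjusted p = 0.678 with an estimated correlation). Actg2 was at 90.5 ± 18.9 against 16.2 ± 11.8 and Cnn1 at 58.6 ± 18.8 against 9.26 ± 8.25 CPM. Paneth cell markers rose in 8 of 13 (list adjusted p = 2.5e-04; adjusted p = 0.659 with an estimated correlation). Itln1 was at 479.8 ± 208 against 30.9 ± 9.92 and Pla2g2a at 950.2 ± 186 against 172 ± 52.4 CPM. Enterocyte markers rose in 5 of 20 (list adjusted p = 0.0104; adjusted p = 0.72 with an estimated correlation), a call that ended without Braf 3 (0.0612) or transgene 1 (0.0765). Lct was at 24.5 ± 26.2 against 0.314 ± 0.276 CPM.

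Khdc1a fell most of the genes that met the rule, to 1.04 ± 0.456 against 274 ± 73.5 CPM (log2 change −7.06, adjusted p = 8.8e-07), and the cystine transporter gene Slc7a11 fell to 8.05 ± 4.81 against 97.6 ± 24.3 CPM. MAPK output was lower than in Braf in 5 of 18 members and higher in 1 (list adjusted p = 7.9e-04; adjusted p = 0.551 with an estimated correlation). Epha2 was at 111 ± 19.3 against 279.9 ± 27.9 and Dusp4 at 31.5 ± 4.50 against 73.1 ± 25.7 CPM. Of 16 fetal and regenerative markers 7 fell and 2 rose (list adjusted p = 0.00157; adjusted p = 0.659 with an estimated correlation). Il1rn was at 104 ± 31.2 against 471 ± 74.8 and Msln at 49.4 ± 18.9 against 251 ± 106 CPM but Ctsl higher at 449 ± 67.3 against 132 ± 23.5 CPM. Cell-cycle inhibitors and p53 targets fell in 4 of 15, or 7 after TMM scaling (list adjusted p = 8.4e-05; adjusted p = 0.659 with an estimated correlation). Phlda3 was at 106 ± 26.4 against 205 ± 22.5 and Cdkn2a at 22.9 ± 14.5 against 70.2 ± 26.1 CPM. Cdkn2a no longer passed without Braf 1 (adjusted p = 0.051), Braf 3 (0.0567), transgene 1 (0.0622) or transgene 2 (0.0623). Intestinal transcription factor genes fell in 4 of 12, with Isx at 31.5 ± 6.05 against 84.3 ± 11.5 and Hnf4a at 280.1 ± 22.0 against 579 ± 232 CPM (list adjusted p = 0.00531; adjusted p = 0.659 with an estimated correlation). Hnf4a did not pass without transgene 3 (adjusted p = 0.0714).

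Between transgene and Braf, 2918 genes changed, 2202 higher and 716 lower (median shift 0.17 log2, and 1700 higher and 1251 lower of 2951 after TMM scaling). The count was 1705 without transgene 3 and 1922 without Braf 2. Mitochondrially encoded genes rose in 7 of 11, or 1 after TMM scaling (list adjusted p = 0.0152; adjusted p = 0.678 with an estimated correlation), a call that ended without transgene 1 (0.0881). The proliferation gene Top2a at 290.2 ± 59.0 against 150.5 ± 37.0 CPM (adjusted p = 0.0608) and the MHC class II gene Cd74 at 197 ± 95.5 against 128 ± 172 CPM (adjusted p = 0.554) did not pass. By chance 10% of unchanged genes show no overlap between 3 and 3 libraries, which is 1 part of the rule for the genes named first here.

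The central question was whether Braf adenomas without Fosl1 differed from those with it, in 6 knockout and 5 Braf libraries of the knockout table. Gstp2 (ENSMUSG00000038155, chromosome 19, 4040285 to 4046023 on the minus strand) rose most of the genes that met the rule, to 47.6 ± 15.1 against 7.19 ± 1.52 nCPM (SD, n = 6 and 5, log2 change 2.54, adjusted p = 1.9e-06), and was the only one of 62 changed genes that passed under every alternative. Chka rose to 145 ± 58.1 against 52.5 ± 10.2 (adjusted p = 0.0147), Gulo, a gene of vitamin C synthesis, to 33.1 ± 20.5 against 7.85 ± 4.46 (adjusted p = 0.0358) and Mup20 to 5.63 ± 3.27 against 0.529 ± 0.342 nCPM (adjusted p = 0.00998). Lactoferrin (Ltf) fell to 1.37 ± 0.961 against 29.5 ± 40.4 (log2 change −2.95, adjusted p = 0.0199), Lcn2 (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252) to 1.70 ± 1.47 against 9.12 ± 5.43 (log2 change −1.96, adjusted p = 0.0129) and the interferon-induced Gbp2 to 2.75 ± 1.10 against 29.4 ± 35.8 nCPM (adjusted p = 0.0199). Sting1, the gene of the innate DNA-sensing adaptor STING, fell to 5.03 ± 2.09 against 20.3 ± 7.02 (log2 change −1.82, adjusted p = 0.00554) and Angptl2 to 2.97 ± 1.48 against 13.4 ± 4.24 nCPM (log2 change −1.88, adjusted p = 0.00444). Plet1 fell to 3.90 ± 2.30 against 61.7 ± 67.4 (adjusted p = 0.0387) and the pore-forming claudin gene Cldn2 to 147 ± 46.6 against 425 ± 220.4 nCPM (adjusted p = 0.0267). Adam8, a matrix protease gene that rose with the transgene, fell to 5.11 ± 2.07 against 13.7 ± 3.21 nCPM (adjusted p = 0.0267).

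**Figure D3:**
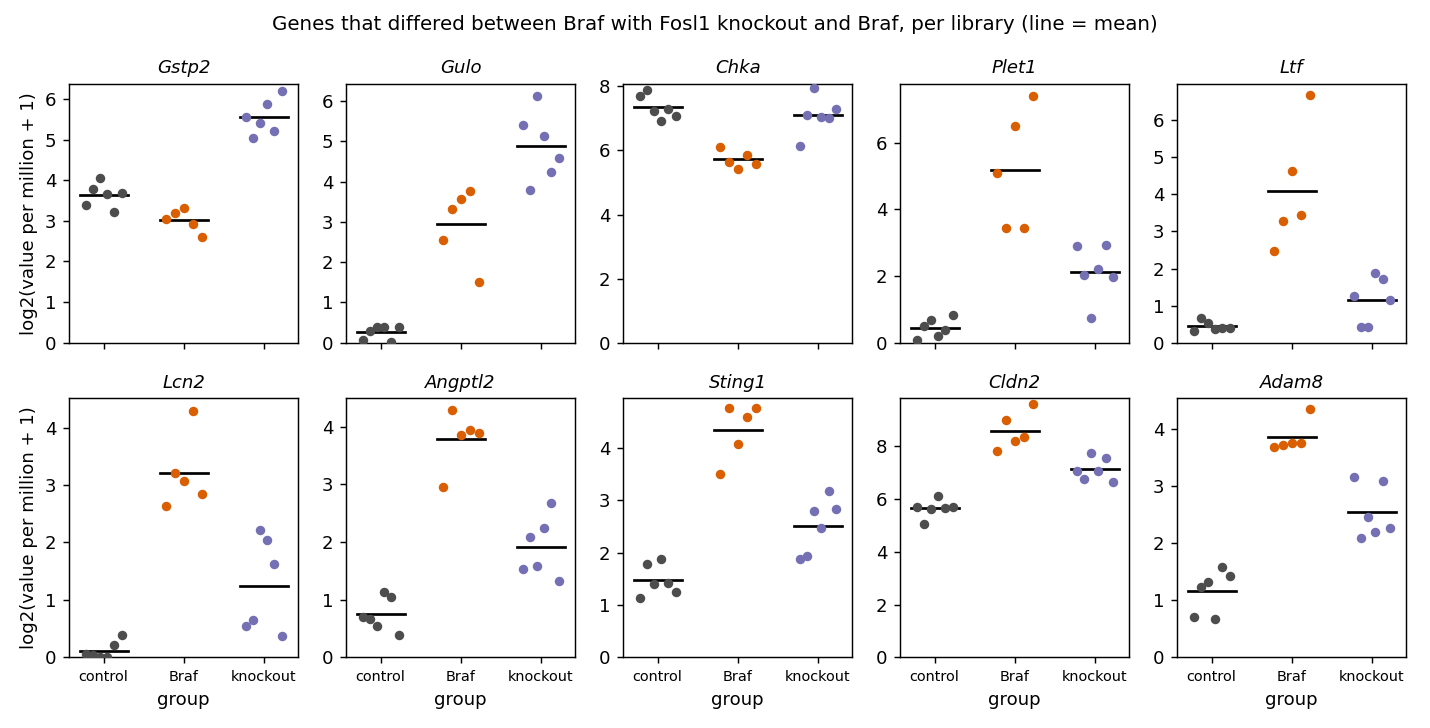
Values of 10 genes in each library of control (n = 6), Braf (n = 5) and Braf with Fosl1 knockout (n = 6), as log2 of nCPM plus 1. Gstp2 averaged 11.6 nCPM in control, 7.19 in Braf and 47.6 in the knockout.

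Among inflammatory mediators, Lcn2, Il1b (0.971 ± 0.925 against 3.87 ± 1.65 nCPM) and Duoxa2 (17.8 ± 7.57 against 79.4 ± 54.3 nCPM) fell, 3 of 14 (1 after TMM scaling), and 9 fell when adjusted over the list alone (list adjusted p = 1.7e-05; adjusted p = 0.453 with an estimated correlation). Interferon response genes fell in 1 of 16 members, and 4 when adjusted over the list alone, with Irf1 at 75.6 ± 21.0 against 129 ± 37.1 nCPM short of the threshold (adjusted p = 0.112; list adjusted p = 1.1e-05, and adjusted p = 0.453 with an estimated correlation). MHC class II genes had 0 of 7 members past the limma threshold over all genes, 6 of 7 at an unadjusted p below 0.05 and 6 lower when adjusted over the list alone (list adjusted p = 0.00126; adjusted p = 0.526 with an estimated correlation). Cd74 was at 47.5 ± 17.9 against 158 ± 56.2 nCPM. Macrophage markers had 0 of 11 past it over all genes, 7 at an unadjusted p below 0.05 and 7 lower when adjusted over the list alone (list adjusted p = 0.00382; adjusted p = 0.453 with an estimated correlation). Lyz2 was at 21.8 ± 13.2 against 51.1 ± 21.7 nCPM. Of 4 neutrophil markers 1 fell (0 after TMM scaling), Csf3r to 0.969 ± 0.243 against 3.82 ± 2.14 nCPM, and 3 were lower when adjusted over the list alone (list adjusted p = 0.0318; adjusted p = 0.453 with an estimated correlation). That call ended without Braf 4 (0.0578), knockout 3 (0.087) or knockout 7 (0.0595). Enterocyte markers were higher as a list although by limma 0 of 20 members passed and 0 were below an unadjusted p of 0.05 (list adjusted p = 6.9e-07; adjusted p = 0.526 with an estimated correlation). Fabp2 was at 1678 ± 1073 against 1066 ± 1616 nCPM. Mitochondrially encoded genes were likewise higher as a list with 0 of 13 passing by limma and 3 at an unadjusted p below 0.05 (mt-Nd2 6382 ± 5261 against 3012 ± 1428 nCPM; list adjusted p = 6.7e-08, and adjusted p = 0.453 with an estimated correlation). Knockout 2 stood apart at a mitochondrial share of 26.1%, where the next knockout library had 10.6%.

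Stem cell, proliferation and mesenchymal lists were lower as lists too, although by limma 0 of their members passed. Stem cell markers had 12 of 14 members below 0, 6 at an unadjusted p below 0.05 and 5 lower when adjusted over the list alone (Prom1 143 ± 54.1 against 426 ± 285 nCPM; list adjusted p = 0.0243, and adjusted p = 0.639 with an estimated correlation). Proliferation genes had 18 of 18 below 0 and 5 at an unadjusted p below 0.05 (Aurkb 15.3 ± 6.68 against 26.8 ± 7.43 nCPM; list adjusted p = 0.0311, and adjusted p = 0.865 with an estimated correlation). Markers of epithelial-to-mesenchymal transition had 9 of 9 below 0 and 3 at an unadjusted p below 0.05 (Fn1 25.8 ± 14.7 against 54.6 ± 24.3 nCPM; list adjusted p = 0.0429, and adjusted p = 0.639 with an estimated correlation). Of 15 genes of xenobiotic and retinol metabolism 0 passed by limma and 0 were below an unadjusted p of 0.05, but the list was higher (adjusted p = 1.7e-04, and adjusted p = 0.526 with an estimated correlation). The stem cell call ended without Braf 5 (0.159), Braf 8 (0.0581) or knockout 7 (0.0704), and the proliferation call without Braf 4 (0.0626), Braf 5 (0.0671), Braf 8 (0.115), knockout 2 (0.0522) or knockout 3 (0.239). With the number in the titles as a replicate block, the proliferation list turned higher, without a call. The mesenchymal call ended without control 4 (0.0503), Braf 4 (0.122), Braf 5 (0.317), Braf 6 (0.0737), Braf 7 (0.0583), knockout 1 (0.104), knockout 2 (0.108), knockout 3 (0.0658) or knockout 7 (0.075).

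Several lists raised in Braf adenomas had no call between knockout and Braf, which does not show that their levels were kept. By limma 0 of 18 MAPK output genes passed, and 3 were at an unadjusted p below 0.05 (list adjusted p = 0.987). Ier3 was at 67.4 ± 14.5 against 83.2 ± 21.4 and Egr1 at 38.6 ± 6.90 against 85.9 ± 61.3 nCPM. Of 16 fetal and regenerative markers, 1 fell (0 after TMM scaling), Ly6c1, to 3.62 ± 2.24 against 12.1 ± 5.70 nCPM (adjusted p = 0.0495), a gene whose reads may be shared with Ly6a and other close relatives. Clu was at 2422 ± 1429 against 4947 ± 2789 nCPM (log2 change −1.03, adjusted p = 0.225; list adjusted p = 0.4). Of 16 Wnt targets 0 passed by limma, 2 were at an unadjusted p below 0.05 and 16 lay below 0 (list adjusted p = 0.244). Lgr5 was at 3.62 ± 6.66 against 19.1 ± 21.7 nCPM. Of 16 gastric markers 0 passed by limma, 4 were at an unadjusted p below 0.05 and 14 lay below 0, with a median log2 change of −0.57 (list adjusted p = 0.138). Tff2 was at 446 ± 223 against 2677 ± 2748 nCPM. Wide spread between libraries left room for differences of several fold in Tff2 and Lgr5.

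Of 14806 tested genes, 62 changed between knockout and Braf, 7 higher and 55 lower. The median gene was 0.15 log2 lower in the knockout, and scaling changed both count and split: 9 higher and 25 lower of 34 with TMM, 8 higher and 18 lower of 26 with median ratios. The changes of Gstp2, Lcn2 and the other genes named above for this comparison exceeded that shift in size. The count of 62 rose to 139 without Braf 4 and 134 without Braf 7, and dropped to 17 without Braf 8, 19 without Braf 6, 19 without knockout 2, 20 without knockout 7 and 30 without knockout 1. Leaving out single controls, which are not part of this contrast but share its estimate of spread, gave 31 without control 5, 29 without control 6, 30 without control 7, 30 without control 8 and 29 without control 9. Under its least favourable alternative the adjusted p was 0.296 for Lcn2, 0.141 for Sting1, 0.111 for Angptl2, 0.197 for Ltf, 0.104 for Chka and 0.287 for Gulo, against 0.0229 for Gstp2.

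Several changed genes lay near Fosl1 on chromosome 19. Within 5 Mb of Fosl1, 9 of 200 tested genes changed (4.50% against 0.363% elsewhere, odds ratio 12.9, Fisher's exact p = 1.4e-07), 2 higher and 7 lower. The 2 higher ones were Gstp2 and Chka, 1402 and 1553 kb from Fosl1. Among the lower ones, Ccdc85b at 17.1 ± 4.66 against 36.8 ± 11.4 nCPM (adjusted p = 0.0288) overlaps Fosl1 on the opposite strand (5453180 to 5457894), and since it is not stated whether counting used the strand, its reads cannot be told apart from reads of Fosl1. The AP-1 family gene Batf2 fell to 19.3 ± 5.79 against 41.1 ± 13.7 nCPM (adjusted p = 0.0472). Gstp1, next to Gstp2 and close to it in sequence, was at 154 ± 38.6 against 286 ± 79.8 nCPM (log2 change −0.87, adjusted p = 0.0826), so reads may have been divided differently between the pair.

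Genes raised by the transgene were then followed in the knockout, in libraries that the 2 tables do not share. Of the 4410 genes at least 2-fold higher with the transgene, 3922 were tested in the knockout table, where their median log2 change from Braf was −0.28 against −0.11 in other genes, and 42 fell while 2 rose (camera p = 2.2e-06, and p = 0.307 with an estimated correlation). Of the 2758 genes at least 2-fold higher in Braf in the transgene table, 2699 were tested, with a median of −0.23 against −0.13 in other genes, and 27 fell while 3 rose (camera p = 0.0128, and p = 0.62 with an estimated correlation). Without knockout 7 the camera p of this second set was 0.321. For the view from the other side the 2-fold limit was dropped, and genes past the adjusted p threshold alone were counted. Of the 54 genes lower in the knockout and tested in both tables, 44 were higher with the transgene (81.5% against 45.9% of all genes, odds ratio 5.22, Fisher's exact p = 1.2e-07). Lcn2, Lrg1 and Adam8 were among them. In Braf against control of the transgene table, 31 of the 54 were higher (57.4% against 34.6%, odds ratio 2.56, Fisher's exact p = 7.9e-04). Fisher's test takes genes as independent, which they are not.

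Knockout and control were compared last, to ask what of the Braf change remained without Fosl1. Clu was still at 2422 ± 1429 against 6.28 ± 1.35 nCPM (SD, n = 6 in each group, log2 change 8.20, adjusted p = 2.6e-12), Atg9b at 1011 ± 562 against 0.941 ± 0.519 and Anxa1 at 383 ± 184 against 1.08 ± 0.415 nCPM. Fetal and regenerative markers rose in 14 of 16 (list adjusted p = 4.2e-08; adjusted p = 0.273 with an estimated correlation). MAPK output rose in 17 of 18, as in Braf (list adjusted p = 2.2e-06; adjusted p = 0.0582 with an estimated correlation). Phlda1 was at 334 ± 42.1 against 9.22 ± 4.52 nCPM. Gastric markers rose in 15 of 16 (list adjusted p = 2.1e-05; adjusted p = 0.334 with an estimated correlation). Anxa10 was at 628 ± 322 against 9.59 ± 5.21 nCPM. Markers of other cells moved as well. Macrophage markers rose in 8 of 11 (list adjusted p = 0.0181; adjusted p = 0.391 with an estimated correlation), fibroblast markers in 10 of 12 (list adjusted p = 0.00754; adjusted p = 0.445 with an estimated correlation), smooth muscle markers in 9 of 10 (list adjusted p = 0.00956; adjusted p = 0.458 with an estimated correlation) and endothelial markers in 8 of 11 (list adjusted p = 0.0254; adjusted p = 0.477 with an estimated correlation). T cell markers fell in 7 of 8 (list adjusted p = 0.00102, and adjusted p = 0.334 with an estimated correlation). Of the fibroblast markers 1 fell, and the sum over that list was lower in the knockout, 244 ± 108 against 313 ± 52.3 nCPM in control. Enterocyte markers fell in 17 of 20 (list adjusted p = 1.8e-07; adjusted p = 0.382 with an estimated correlation). Lct was at 14.6 ± 33.1 against 2064 ± 236 nCPM. Knockout 7 carried most of that mean, at 6.38 on the log2(value + 1) scale, where the next knockout library had 1.36. Lct passed in every alternative except the replicate block, where its adjusted p was 0.0654.

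Interferon response genes, of which 7 rose (4 after TMM scaling) and 1 fell in Braf against control, had 1 lower and the rest not passing here, or 2 lower after TMM scaling. Irf1 fell to 75.6 ± 21.0 against 187 ± 41.4 nCPM (adjusted p = 2.1e-05), while Cxcl9, higher in Braf at 16.0 ± 11.3 against 0.765 ± 0.555 nCPM, stood at 4.58 ± 4.88 against 0.765 ± 0.555 nCPM against control in the knockout (adjusted p = 0.0633), and its difference between knockout and Braf did not pass (adjusted p = 0.169). MHC class II genes fell in 2 of 7, or 5 after TMM scaling (list adjusted p = 0.033; adjusted p = 0.466 with an estimated correlation), a family in which reads may be shared between close relatives. H2-DMa was at 4.36 ± 0.911 against 17.7 ± 17.9 nCPM (adjusted p = 0.00573). That list was no longer called without control 8 (adjusted p = 0.0813) or without knockout 7 (adjusted p = 0.0506). In all, 8409 genes changed between knockout and control, 5535 higher and 2874 lower, with a median shift of 0.27 log2 and 4184 higher and 4426 lower of 8610 after TMM scaling. Braf itself was at 20.3 ± 3.24 against 11.5 ± 1.25 nCPM in knockout against control (adjusted p = 4.7e-04) and differed little between knockout and Braf (log2 change −0.16, adjusted p = 0.683). Braf against control was at 23.0 ± 5.96 against 11.5 ± 1.25 nCPM in the same table (adjusted p = 1.1e-04) and at 18.1 ± 1.38 against 11.2 ± 1.58 CPM in the transgene table (adjusted p = 0.0316). With the transgene Braf was at 19.4 ± 5.52 CPM, at an adjusted p of 0.0169 against control and 0.878 against Braf adenomas. The calls for Braf in the transgene table ended after TMM scaling. The first also ended without control 1 (adjusted p = 0.11), control 2 (0.0727), Braf 1 (0.0506), Braf 2 (0.0738) or Braf 3 (0.0664), and the second without control 1 (0.0656), transgene 2 (0.0581) or transgene 3 (0.0732).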

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

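Tests of explanations below were chosen after the result was seen, except the counts over other splits of the samples and the reads of Gstp1 and Gstp2. Single libraries were compared with the rest of their group of 5 or 6 in the knockout table. In 25 of 168 groups of values the highest or lowest library stood apart from the others, where chance gives about 5%. These were 10 of 51 measures of the libraries and 15 of 117 genes.

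Control 4 had the fewest genes at 1 nCPM or more (12425) and a TMM factor of 0.708, each apart from the other controls. Control 6 stood apart in erythroid genes (258 nCPM), control 8 in MHC class II genes (1751 nCPM) and control 9 in endothelial genes (6.73 nCPM). In Braf 6 noncoding RNAs were at 73.7 nCPM, and in knockout 1 pancreatic acinar genes at 266 nCPM. Knockout 2 was apart in its estimated depth (4.12 M reads), its mitochondrial share (26.1%) and the share of its 20 most abundant genes (37.8%). No explanation was tested for the control and Braf libraries.

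On the log2(value + 1) scale, single controls stood apart for Tnfrsf11b (0.69 in control 9), Slc5a12 (6.83 in control 7), Slc28a3 (4.06 in control 4), Khdc1a (0.29 in control 5), Stra6 (0.21 in control 6) and Apol10a (4.30 in control 7). The values of Khdc1a in control 5 and Stra6 in control 6 lay below the level of 3 reads in these libraries. Among Braf libraries, Atg9b (8.55 in Braf 7), Khdc1a (2.70 in Braf 5) and Apol10a (2.46 in Braf 4) stood apart. Knockout 7 was apart for 6 genes: Tff2 (6.52), Lct (6.38), Enpep (6.64), Naaladl1 (4.16), Slc13a2 (5.56) and Slc5a12 (1.33). In the library left out of the comparisons, Clu was at 2721 nCPM where the highest control had 8.02.

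Changed genes of knockout against Braf clustered near Fosl1, 9 of 200 within 5 Mb (odds ratio 12.9). Loss of a piece as long as that window would bring the neighbours down together. The median of the 200 genes, however, lay 0.00513 log2 from that of all genes (interquartile range 0.445). A shorter loss would hardly move that median and was not tested. Under 1 Mb from Fosl1 6 of 87 genes changed, and 3 of 113 at 1 to 5 Mb. A segment of another strain carried along with the floxed allele may account for the cluster. Also among neighbours that did not pass, 41 of 191 had an unadjusted p below 0.05 (21.5% against 14.0% elsewhere, odds ratio 1.67, Fisher's exact p = 0.0062). For Gstp2, reads may have moved from Gstp1, which changed by −132 nCPM where Gstp2 gained 40.4. An effect of the deletion on its neighbours was not tested and stays open beside these.

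The 55 genes lower in the knockout had a median log2 change of −1.39 (interquartile range 0.701), and 54 of them were higher in Braf than in control. Choosing genes by high values in the same Braf libraries favours such a count. More normal epithelium in the knockout libraries would explain a median of only −0.0953 at the mean estimated share of 8.97 ± 17.2%. At the highest share it would explain −0.35. That share placed the enterocyte genes of a library on a scale from the Braf mean to the control mean. It is thus relative to Braf and not a tissue fraction. Of the 55 genes, 19 lay below both Braf and control. Without knockout libraries 1 and 2 the median was −1.31 and all 55 were still lower. These genes had been chosen with those 2 libraries included, which favours that result, and most no longer passed without them. Fewer immune cells may account for part of the falls, as 35 of 38 immune markers were lower, with a median of −0.80 (interquartile range 0.845), and this cannot be told apart from lower expression in the tumour cells because both move the same genes in bulk tissue. A loss of Fosl1 acting on these genes stays open as well, as do labels that Fosl1 itself could not check here.

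Fibroblast, endothelial, smooth muscle and mesenchymal genes lay above 0 with the transgene against Braf in 43 of 44, with a median log2 change of 2.47, and 12 of 12, 10 of 12, 7 of 9 (6 after TMM scaling) and 10 of 12 of them passed. A lower share of epithelium would raise all other cell types alike, but fibroblast markers (median 3.08, interquartile range 1.13) exceeded T cell markers (0.51, 0.678) by 2.57. T cell markers had fallen along with enterocyte markers in Braf against control, so they may not stand for cells outside the epithelium. Macrophage markers, at 1.33 (1.14), also lay below the fibroblast markers. These differences speak against a lower share of epithelium as the only cause. Part of the rise may still come from it, since medians of B and plasma cell (2.30), erythroid (2.37), adipocyte (1.35), neutrophil (1.27), enteric neuron (0.70) and mast cell markers (0.38) were above 0 as well. The 1 added before the log2 also shrinks changes of the low T cell markers. The scaling of the deposited values would need the difference to vanish after TMM rescaling, where it was 2.29 with all genes shifted by 0.166. More stroma in these adenomas and stromal expression in tumour cells may each be the source and were not tested. Nor were doxycycline, fed to the transgene group only, and the kit, which is not given for each library.

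With 3 against 3 libraries, 10 splits are too few for a share under 0.05. The real counts of 7751, 9743 and 2918 genes stood against at most 3, 0 and 1 in other splits, so 1 of 10 was as large in each. For lists the real counts of 25, 22 and 17 stood against at most 25, 25 and 26, and 3, 3 and 4 of 10 splits were as large. For each comparison of the knockout table, 100 splits were drawn. Chance was excluded for the genes of Braf against control (9117 against at most 3301 in other splits, 1 of 100 as large). It was also excluded for those of knockout against control (8409 against 4290, 1 of 100). For the lists of Braf against control 2 of 100 splits were as large, a share under 0.05. Another split also called 32 lists, the real count, so chance was not excluded for them.

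Chance was not excluded for the 62 genes of knockout against Braf, because 5 of 100 splits called as many, up to 1183. The splits calling 894, 284, 1183 and 643 genes point to a structure of the samples. All 4 were among the 20 other splits that kept Braf 7, knockout 3 and knockout 7 in 1 group, and none of the 79 that parted these 3 called as many as 62. These 3 had the highest estimated shares of normal epithelium in the comparison, 27.7% to 34.9% on the scale from the Braf mean to the control mean. But they were singled out after the counts were seen, and whether that share is the cause was not tested. Nor was chance excluded for the 13 lists of that comparison (at most 22 in other splits, 48 of 100 as large) or the 28 of knockout against control (at most 33, 10 of 100). The same held for the transgene-raised genes in the knockout (median −0.17 from other genes, at most 0.257 in size elsewhere, 16 of 100) and the Braf-raised genes (−0.10, 0.239, 41 of 100).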

How the results depend on the processing

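Chosen only after the data were seen were edgeR and DESeq2 on recovered reads, the fits without knockout libraries 1 and 2 or without the 3 libraries of highest mitochondrial share, and rescaling without mitochondrial genes. In 5 of the 6 comparisons, all but knockout against Braf, the count of changed genes stayed within 1.5 times its value under every alternative other than leaving out single libraries. Leaving out 1 library at a time gave 6304 to 7857 genes for Braf against control in the transgene table, 8383 to 9918 for transgene against control, 8323 to 9484 for Braf against control in the knockout table and 7774 to 8750 for knockout against control. Transgene against Braf moved further, from 1705 (without transgene 3) to 3089 (without Braf 3), against 2918. On recovered reads edgeR gave 7643, 8931 and 2142 genes and DESeq2 8148, 9284 and 3507, in the order of Braf against control, transgene against control and transgene against Braf.

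The 62 genes of knockout against Braf depended on most choices. They became 25 with a pseudocount of 0.25, 21 with a filter at 5 nCPM (fewer genes tested), 34 with TMM and 26 with median-ratio rescaling. The 2 groups alone gave 2, and 37 passed after rescaling without mitochondrial genes. The fit of the 2 groups had fewer libraries to estimate the spread and left out the controls. Replicates correlated at 0.973 to 0.986 in controls, against 0.908 to 0.962 in Braf and 0.904 to 0.972 in the knockout. Controls may thus have lowered the shared estimate of spread, and the 2 reasons were not told apart. Without knockout libraries 1 and 2, and equally without the 3 libraries of highest mitochondrial share, 6 passed, with fewer libraries in each. Array weights (42), a pseudocount of 5 (56) and no filter (69) stayed within 1.5 times. Leaving out 1 library gave 17 (without Braf 8) to 139 (without Braf 4). The cause of these differences was not tested.

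The list calls rested on the preset correlation. With an estimated correlation in camera 0 lists passed in each of the 6 comparisons (6, 7, 2, 8, 2 and 7 at an unadjusted p below 0.05), against 25, 22, 17, 32, 13 and 28 with camera at the preset one and 32, 32, 16, 38, 5 and 37 with fry. Leaving out 1 library gave 23 to 27, 22 to 27, 13 to 25, 32 to 34, 8 (without Braf 5) to 17 (without Braf 8) and 28 to 30 lists. The set of transgene-raised genes in the knockout had p = 0.307 with an estimated correlation and 1.2e-08 to 0.011 without single libraries. The set of Braf-raised genes had p = 0.62 with an estimated correlation, 0.107 with fry and 0.0654 with a filter at 5 nCPM. Without single libraries its p was 1.5e-04 (without Braf 7) to 0.321 (without knockout 7), and the cause was not tested. Genes that moved alike and by at least 2-fold numbered 3635 of 6524 for Braf in both tables and 3584 of 6578 for transgene and Braf, since a stricter limit leaves fewer. The 2 rises of Fosl1 over control kept their calls with pseudocounts of 0.25 (log2 change 4.26 and 3.92) and 5 (0.93 and 0.77).

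Correlations between libraries with the same number in their titles ran from −0.184 to 0.371, and not every pair was above 0.1, so the numbers were not taken to pair the samples. With that number as a replicate block, on the libraries whose numbers occur in both groups, 16 genes and 23 lists passed for knockout against Braf. In the replicate block, 2 lists of that comparison changed direction: goblet markers were lower (adjusted p = 0.00212, against higher at 0.987) and proliferation higher (0.723, against lower at 0.0311). The replicate block gave 6862, 10145, 2041, 8119 and 6920 genes in the other comparisons, and the cause of the differences was not tested.

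Of the named genes that passed, and of all 62 changed genes for knockout against Braf, 112 of 114, 100 of 104, 54 of 78, 140 of 141, 1 of 62 and 118 of 124 passed under all alternatives run, in the order of Braf and transgene against control, transgene against Braf, and then Braf against control, knockout against Braf and knockout against control. Depth limited what could be called for low genes: 3 reads stood for 0.206 to 0.225 CPM in the transgene table, and knockout library 2 had the lowest estimate, 4.12 M reads.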

Other observations

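One library of the knockout table had a title naming the Fosl1 knockout and a genotype, source and column naming Braf, and it entered no comparison. Across genes its log2 values correlated at 0.776 with the control mean, 0.974 with the Braf mean and 0.952 with the knockout mean. Of the 62 genes that changed between knockout and Braf, it was closer to the Braf mean in 51 and to the knockout mean in 11. It had Gstp2 at 5.10, Chka at 58.3, Gulo at 8.63, Ltf at 39.6, Plet1 at 94.6, Lcn2 at 1.85, Angptl2 at 4.89 and Sting1 at 7.90 nCPM.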
